A study of Homo sapiens with 6 samples.

How the data were processed

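Total RNA of ALL-SIL cells was sequenced in 6 libraries, 3 from cells treated with JQ1 and 3 from DMSO controls. Per the labels' protocols the cells grew in medium with 20% fetal bovine serum, RNA was taken with a column kit that also keeps small RNA, and libraries were made with a stranded total RNA kit. The treatment text of every sample, the controls included, repeats the JQ1 dose of 1 µM and time of 24 h; the groups were taken from the sample titles, and the exposure of the controls to DMSO is not described separately. The genome build was GRCh38, per the submitters' processing notes. The aligner, its version, the annotation release and any read trimming are not given in the sources used here.

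Each deposited file holds raw counts of reads per gene, not normalised, in 3 columns: without regard to strand, and for each strand. The layout is that of the gene counts written by the STAR aligner, which leaves out reads that map to several places or to several genes, so genes with near-identical copies (histones, ribosomal protein genes, HSPA1B, CASTOR3P) are undercounted and uncertain. The column for the reverse strand was used, since it held 20.9 to 22.6 times the gene counts of the other strand. The first 4 lines of each file are read classes and stayed out of all totals: 1.48% to 1.99% of reads were unmapped, 14.1% to 15.7% mapped to several places, 18.8% to 26.1% lay in no gene and 3.38% to 3.88% were ambiguous. The files list 58096 genes by versioned Ensembl identifier, of which 53747 matched GENCODE release 29 with their version and 57492 without; 604 did not match and held at most 0.0327% of gene counts. Positions are printed only for genes whose version matched. No 2 libraries of a group agreed within sampling noise in a chi-square comparison of their counts.

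Gene counts per library ran from 15925885 to 25293884. At this depth 1 CPM is about 16 to 25 reads, and a gene needed about 10 reads in at least 3 libraries to be tested. A tested gene can therefore have far fewer reads in 1 group, such as BCL2A1 with 2, 3 and 1 reads in JQ1 replicates 1, 2 and 3. Intervals on counts summed over a group leave out the spread between libraries. The reads carry no molecular identifiers, so such intervals may not cover all of the counting error either.

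Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 13975, and scaled by TMM factors (0.965 to 1.06). Differences between groups were tested with edgeR 4.0.16 (glmQLFit and glmQLFTest, robust, group only) in R 4.3.3, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05; SE is the size of the log2 fold change divided by the square root of F. The common biological coefficient of variation was 0.126. Before the data were examined, 38 gene lists were fixed, together with the design, the alternatives and the rule for named genes. Lists with at least 5 tested members (33) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, then with an estimated correlation and with fry, which asks whether a list's genes move on balance 1 way and does not compare them with other genes. The named genes were a fixed set of genes (among them MYC, HEXIM1, SERPINI1, BRD2, BRD3, CDK6, BCL2, BCL2L11, MCL1, IL7R, TLX1, NOTCH1, MYB, CDKN1A, TXNIP, PVT1, LUNAR1, MALAT1 and NEAT1); the 10 protein-coding genes per direction with the largest called change, at least 5 CPM in the higher group and groups that do not overlap; the 5 lncRNA genes per direction with at least 1 CPM under the same rule; and up to 4 members per list with the smallest p, with the most abundant member of each list of other cell types. Y-linked genes and XIST were left out of that choice, and some results for genes that the rule names are not reported here. Genes were called lncRNA by their GENCODE biotype. Shares of counts were compared with 2-sided exact permutation tests.

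The groups share replicate numbers in the titles. Deviations from the group means correlated between libraries of the same number (0.33, 0.43 and 0.37 for numbers 1, 2 and 3, across genes), so libraries of the same number can be taken as pairs. The main tests used the group only and leave this pairing out. The pairing comes from the data, since the labels do not say what a number marks. A fit with the number as a block was an alternative, and its common biological coefficient of variation was 0.0595.

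The alternatives were DESeq2 1.42.0, limma-voom, relative log expression factors, upper-quartile factors, library size only, no filter on low counts, at least 1 CPM in at least 3 libraries, unstranded counts, mitochondrial and small RNA genes left out, the replicate block, a test against a fold change of 1.5, and each library left out in turn. The procedure was tested on simulated data with the real means, library sizes and dispersions and 200 changed genes among 13975. At 2-fold 68% of 100 changed genes were recovered, at 1.5-fold 51% of 100, and 9 unchanged genes were called, 7.03% of calls. The real comparison called 5110 genes, and the simulation held no link between libraries of the same number. These rates therefore need not hold for the real comparison. With no simulated change 0 of 33 lists were called, in genes simulated independently of each other. Gene length and GC content came from GENCODE release 29 transcripts. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9, and overlaps of genes on the opposite strand with GenomicRanges 1.54.1.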

Results

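Total RNA was sequenced from ALL-SIL, a human T-cell acute lymphoblastic leukaemia (T-ALL) line that carries a TLX1 rearrangement and a NUP214-ABL1 fusion, after exposure to JQ1, a small molecule that displaces BET bromodomain proteins from acetylated chromatin. The labels gave 3 libraries for JQ1 (1 µM for 24 h) and 3 for DMSO, the solvent control, numbered 1 to 3 in each group. The libraries keep the strand of the RNA, and reads were counted on the sense strand of genes. The depth was 24857219, 22109783 and 15925885 gene counts in JQ1 replicates 1, 2 and 3, and 20391040, 25293884 and 24867762 in DMSO replicates 1, 2 and 3. The labels do not say whether the replicates of a group were separate cultures, so the p-values measure the spread between these libraries, which may be technical. Levels are in CPM, the gene's count scaled to the normalised library size, as mean ± SD over n = 3 libraries, and fold changes are log2 of JQ1 over DMSO ± standard error (SE). Positions and biotypes come from GENCODE release 29 on GRCh38. Gene names come from a separate list of symbols, with the names of that release where the list gave none or a duplicate.

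The comparison asked which RNAs change when BET proteins are displaced in these leukaemia cells. Among the largest falls in protein-coding genes with at least 5 CPM in the higher group was that of CCR8, a chemokine receptor. CCR8 (ENSG00000179934.6, chromosome 3, 39329706 to 39333511) fell from 22.0 ± 3.30 to 0.691 ± 0.296 CPM, a log2 change of -4.97 ± 0.25 (edgeR adjusted p = 3.9e-06). RGL4, CD1A, IGLL1, CD244, TRPM2, DNTT, TMEM229B and ALDH3B2 had log2 changes between -4.90 and -4.07. Some rest on few JQ1 reads, so their size is uncertain: RGL4 had 669 counts in DMSO and 19 in JQ1, and ALDH3B2 had 373 and 18. IGLL1 had 62, 535 and 253 counts in DMSO replicates 1, 2 and 3, and 6, 11 and 8 in JQ1. The RGL4 change was -0.96 when both strands were counted together. The largest rises were smaller, with IRF7 (ENSG00000185507.19), a transcription factor of the interferon system, at 4.55-fold (7.45 ± 1.87 to 33.8 ± 5.55 CPM, log2 change 2.19 ± 0.19, edgeR adjusted p = 4.2e-05). IZUMO4, CASTOR3P, CEMIP2, DOCK4, FGD6, DCXR, SMIM14, LZTS3 and RGS2 rose by log2 changes between 1.64 and 2.06. All these falls and rises were chosen among genes whose groups did not overlap, so the lack of overlap is no added support.

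**Figure D1:**
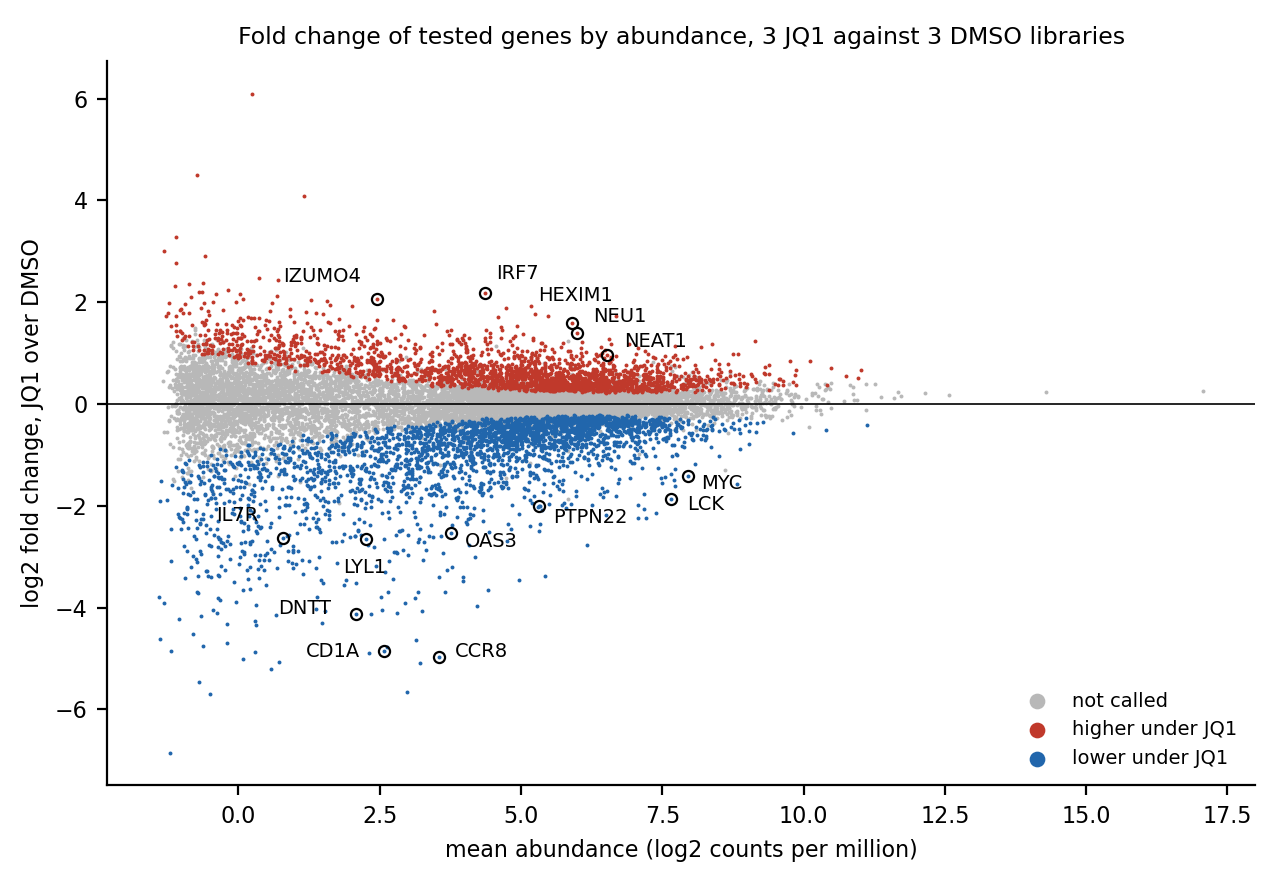
Each point is a tested gene, with its mean abundance in log2 CPM on the horizontal axis and its log2 fold change (3 JQ1 over 3 DMSO libraries) on the vertical axis; Y-linked genes and XIST are not drawn. Red and blue mark edgeR adjusted p under 0.05, grey the rest, and falls such as CCR8 at -4.97 and CD1A at -4.85 reach further from 0 than rises such as IRF7 at 2.19.

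In all, 2227 genes were higher and 2883 lower under JQ1 among 13975 tested (edgeR adjusted p under 0.05). Falls were the larger changes, with 1063 genes lower and 389 higher by more than 2-fold, a ratio of 2.73. Of the protein-coding genes, 1812 of 10667 rose and 2589 fell. The groups did not overlap for 48.9% of tested genes, where chance gives 10%. These counts leave out the pairing of libraries by replicate number. With the number as a block 3813 genes were higher and 4133 lower. Against a fold change of 1.5 in place of no change, 246 genes were higher and 899 lower.

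MYC (ENSG00000136997.15), an oncogene that drives growth in T-ALL, fell from 358 ± 12.1 to 135 ± 14.8 CPM, which is 2.65-fold (log2 change -1.41 ± 0.10, edgeR adjusted p = 1.4e-05). HEXIM1, the inhibitor of the elongation kinase P-TEFb whose RNA is a common readout of BET inhibition, rose 3.01-fold from 29.8 ± 7.17 to 89.3 ± 19.2 CPM (log2 change 1.59 ± 0.21, edgeR adjusted p = 0.00066). HEXIM1 (ENSG00000186834.3) lies on chromosome 17, 45148502 to 45152101. SERPINI1, another such marker, rose by a log2 change of 0.81 ± 0.27 (edgeR adjusted p = 0.037), a call that was lost without JQ1 replicate 1, JQ1 replicate 2, DMSO replicate 2 or DMSO replicate 3 (0.72 to 0.75, edgeR adjusted p from 0.094 to 0.12), with DESeq2 (adjusted p = 0.052) and with library size as the only scaling (edgeR adjusted p = 0.052). The histone gene H2BC21 rose by 0.47 ± 0.12 and BCL2, an apoptosis inhibitor, fell by 0.54 ± 0.13. Of 9 tested BET inhibitor marker genes 3 rose and 4 fell (3 and 5 adjusted over the list alone). The list as a whole was not called by camera (adjusted p = 0.77, and 0.88 with an estimated correlation) but was called lower by fry (adjusted p = 0.04).

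Among the BET genes themselves, BRD2 rose from 357 ± 45.8 to 531 ± 91.4 CPM (log2 change 0.57 ± 0.15, edgeR adjusted p = 0.011). BRD3 (0.17 ± 0.09, edgeR adjusted p = 0.17) did not pass the test. CDK9, the P-TEFb kinase, rose by 0.51 ± 0.09, while NELFCD, a subunit of the pausing factor NELF, fell by 0.93 ± 0.09 and HEXIM2 had a log2 change of -1.47 ± 0.23 (edgeR adjusted p = 0.00072). The HEXIM2 change was -0.27 (edgeR adjusted p = 0.42) when both strands were counted together. Of 19 tested P-TEFb, elongation and BET genes 4 rose and 3 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.45). In this list the block called 6 higher and 5 lower.

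MYC target genes fell together. Of 50 tested, 39 fell and 0 rose (42 and 0 adjusted over the list alone), with a median log2 change of -0.60 (camera adjusted p = 4.2e-10, and adjusted p = 0.86 with an estimated correlation). SLC19A1, the folate carrier, fell by 1.38 ± 0.15 and the nucleolar genes NOP16, WDR74 and WDR43 fell by 1.18 ± 0.11, 0.98 ± 0.11 and 0.86 ± 0.10. Genes of ribosome biogenesis and RNA polymerase I moved the same way, with 20 of 29 lower and 0 higher (21 lower adjusted over the list alone; median -0.51, camera adjusted p = 1.1e-06, and adjusted p = 0.86 with an estimated correlation). RRS1 fell by 1.32 ± 0.13, POLR1B, the second largest subunit of RNA polymerase I, by 1.13 ± 0.11, WDR12 by 0.85 ± 0.11 and NHP2 by 0.68 ± 0.08. Few genes of cytoplasmic ribosomal proteins passed the test: 2 of 44 rose and 1 fell (1 and 0 adjusted over the list alone; camera adjusted p = 0.21), with RPL12 higher by 0.59 ± 0.11. The block called 11 of them higher and 2 lower, and the list was called higher without JQ1 replicate 3 (camera adjusted p = 0.041) and without DMSO replicate 1 (0.033), with adjusted p = 0.88 with an estimated correlation over all libraries.

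Metabolic genes were mixed. In nucleotide and polyamine synthesis 11 of 27 genes fell and 2 rose (11 and 4 adjusted over the list alone; camera adjusted p = 0.21). NME1, a nucleoside diphosphate kinase, fell by 1.48 ± 0.13, DHODH of pyrimidine synthesis by 0.96 ± 0.14 and ADSL of purine synthesis by 0.55 ± 0.08, whereas IMPDH2 of guanine nucleotide synthesis rose from 277 ± 11.2 to 447 ± 26.4 CPM. With the block 7 members were higher and 14 lower. In glycolysis 8 of 21 genes fell and 2 rose (8 and 3 adjusted over the list alone). The glycolysis list was called lower by fry (adjusted p = 0.018) but not by camera (adjusted p = 0.15, and 0.86 with an estimated correlation). HK2, which phosphorylates glucose, fell by 1.48 ± 0.23, the lactate exporter SLC16A3 by 1.39 ± 0.25, the glucose carrier SLC2A3 by 0.92 ± 0.17 and ALDOA by 0.53 ± 0.10. Of 32 nuclear genes of the mitochondrial respiratory chain 10 fell and 0 rose (the same adjusted over the list alone; camera adjusted p = 0.067), led by NDUFB10 (-0.75 ± 0.08) and NDUFB8 (-0.66 ± 0.10) of complex I. That list was called lower without DMSO replicate 2 (camera adjusted p = 0.048), with library size as the only scaling (0.033), with no filter on low counts (0.031), with unstranded counts (0.026) and by fry (0.018), and had adjusted p = 0.86 with an estimated correlation over all libraries. Cholesterol synthesis and uptake had 3 of 22 genes higher and 0 lower (2 and 0 adjusted over the list alone), among them TM7SF2 (1.46 ± 0.16) and LSS (0.93 ± 0.16). The cholesterol list was not called (camera adjusted p = 0.13), but was called higher with the block (0.033, with 11 genes higher and 2 lower), with no filter on low counts (0.04), without JQ1 replicate 3 (0.0035) and without DMSO replicate 2 (0.049). With an estimated correlation over all libraries it had a camera adjusted p = 0.86.

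Genes of T-cell identity fell. Of 20 tested thymocyte stage markers 15 fell and 0 rose (16 and 0 adjusted over the list alone), with a median log2 change of -1.56 (camera adjusted p = 1.1e-06, and adjusted p = 0.65 with an estimated correlation). CD1A, a lipid-presenting molecule of cortical thymocytes on chromosome 1 (158254137 to 158258269), fell by 4.85 ± 0.32, and CD1B, of the same family, fell by 3.90 ± 0.33. The homing receptor CCR7 fell by 2.36 ± 0.20 and the co-receptor gene CD8A by 1.65 ± 0.13. DNTT, the template-independent polymerase of receptor gene rearrangement, fell from 7.46 ± 3.65 to 0.447 ± 0.261 CPM. Of 29 genes of the T-cell receptor complex and its signalling 20 fell and 1 rose (the same adjusted over the list alone; median -0.80, camera adjusted p = 1.7e-05, and adjusted p = 0.86 with an estimated correlation). The receptor-proximal kinase LCK fell from 314 ± 6.69 to 86.5 ± 17.1 CPM (log2 change -1.86 ± 0.13, edgeR adjusted p = 1.3e-05), the phosphatase PTPN22 by 2.01 ± 0.13, the adaptor LCP2 by 1.42 ± 0.13 and SIT1 by 1.54 ± 0.15.

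**Figure D2:**
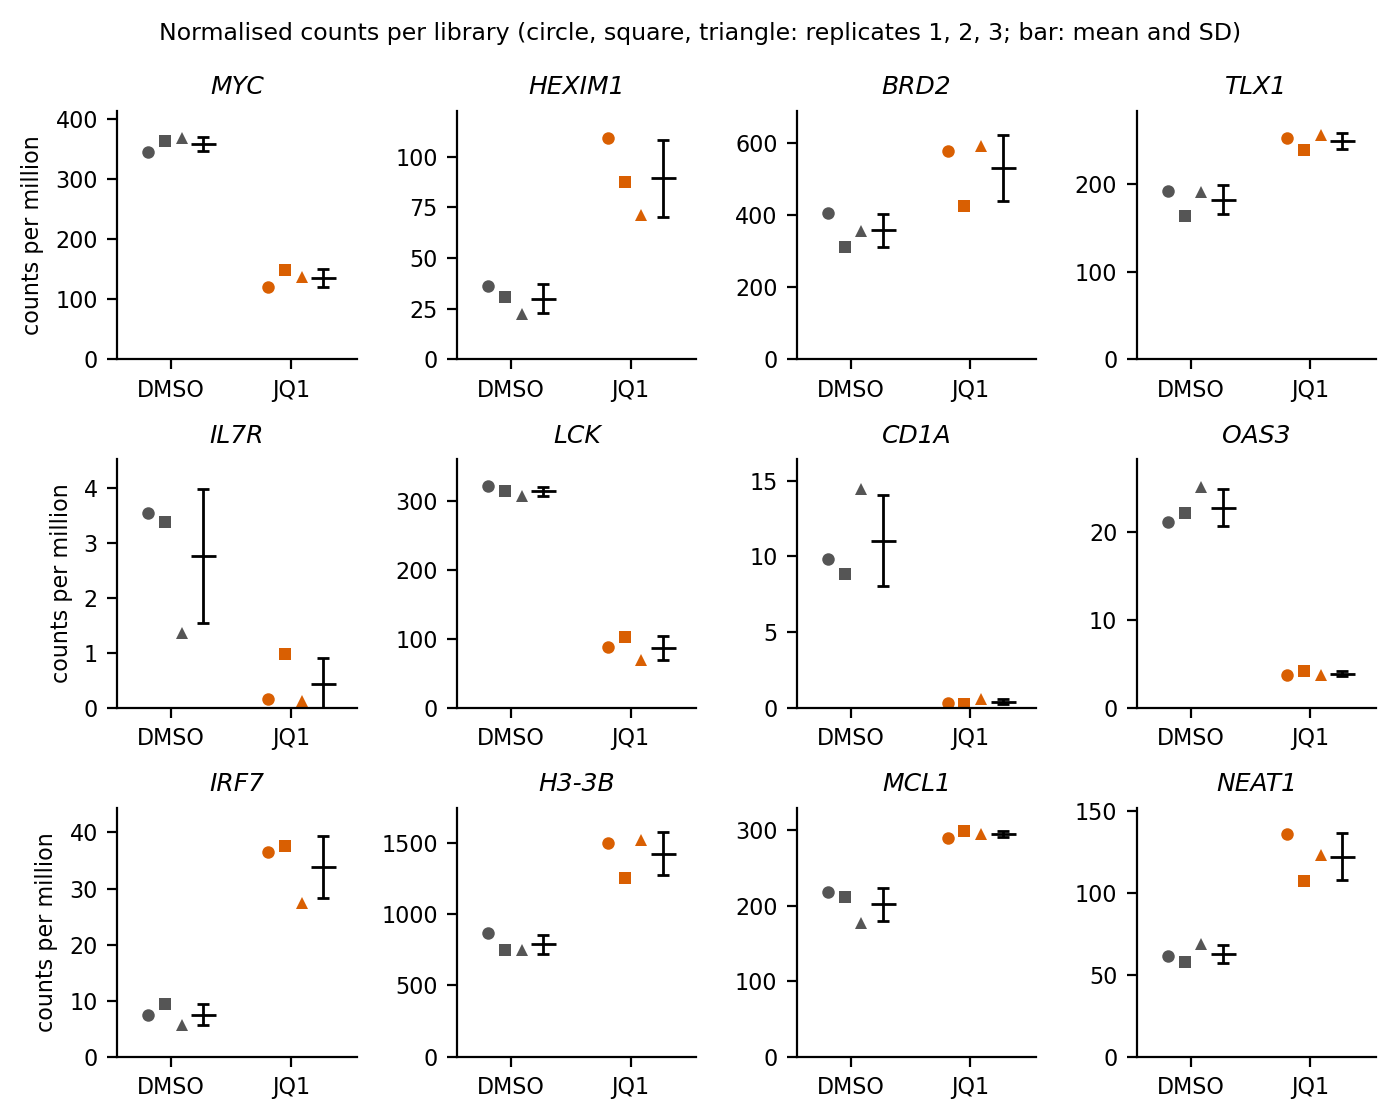
Normalised levels in CPM are shown for 12 genes in each of 3 DMSO (grey) and 3 JQ1 (orange) libraries, with mean and SD beside them; the vertical axis is linear and starts at 0, where the IL7R error bar ends. MYC, LCK, CD1A and OAS3 lie lower in every JQ1 library than in any DMSO library, and HEXIM1, IRF7, H3-3B and NEAT1 lie higher.

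TLX1, the rearranged oncogene of this line (ENSG00000107807.12, chromosome 10, 101130505 to 101137789), did not fall with the T-lineage genes. It rose 1.37-fold, to 249 ± 8.93 CPM (log2 change 0.45 ± 0.10, edgeR adjusted p = 0.0045). Among T-ALL transcription factors and oncogenes 9 of 26 fell and 4 rose (10 and 4 adjusted over the list alone). The camera adjusted p was 0.11, with 0.036 without JQ1 replicate 3, 0.037 with no filter on low counts and 0.86 with an estimated correlation. In this list the block called 4 higher and 14 lower. The helix-loop-helix factor LYL1 fell by 2.66 ± 0.23 and WT1 by 0.99 ± 0.10, while NOTCH3 rose by 1.06 ± 0.13. MYB had a log2 change of -0.10 ± 0.13 (edgeR adjusted p = 0.58), from -0.27 to -0.01 in fits without a library. NOTCH1 rose by 0.49 ± 0.16 (edgeR adjusted p = 0.038), a call lost without JQ1 replicate 2, JQ1 replicate 3, DMSO replicate 1 or DMSO replicate 2 (0.37 to 0.55, edgeR adjusted p from 0.053 to 0.12) and with library size as the only scaling (0.42, edgeR adjusted p = 0.069). Of 14 NOTCH1 target genes 5 fell and 3 rose (6 and 5 adjusted over the list alone, camera adjusted p = 0.45). Besides MYC and NOTCH3 they included TRIB2 (-0.71 ± 0.12) and GIMAP5 (-1.53 ± 0.29). Under the block 5 NOTCH1 target genes were higher and 7 lower.

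IL7R, the interleukin-7 receptor chain, fell from 2.76 ± 1.21 to 0.425 ± 0.485 CPM (log2 change -2.64 ± 0.65, edgeR adjusted p = 0.013), and the log2 change was -4.16 without JQ1 replicate 2. IL2RB fell by 1.88 ± 0.23, IL2RG by 0.76 ± 0.12 and the cytokine gene OSM from 45.4 ± 8.03 to 8.83 ± 2.85 CPM. The list of IL7R, JAK-STAT and ABL signalling as a whole was mixed, with 9 of 29 lower and 4 higher (the same adjusted over the list alone). Its camera adjusted p was 0.63, and under the block 10 genes were higher and 12 lower. CDK6, a cell-cycle kinase abundant in these cells, fell from 1576 ± 282 to 1110.4 ± 228 CPM (-0.51 ± 0.17, edgeR adjusted p = 0.043), a call lost without JQ1 replicate 1, JQ1 replicate 2, DMSO replicate 1 or DMSO replicate 3 (-0.55 to -0.35, edgeR adjusted p from 0.069 to 0.14).

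Interferon-response genes fell although IRF7 rose. Of 30 tested 18 fell and 3 rose (20 and 3 adjusted over the list alone; median -0.56, camera adjusted p = 0.0015, and adjusted p = 0.86 with an estimated correlation). The antiviral synthetase OAS3 fell from 22.7 ± 2.06 to 3.89 ± 0.287 CPM, OAS2 from 22.7 ± 0.779 to 6.21 ± 0.663 CPM and XAF1 by 2.17 ± 0.19. Of 14 NF-kB target genes 8 fell and 1 rose (the same adjusted over the list alone; median -0.70, camera adjusted p = 0.003, and adjusted p = 0.86 with an estimated correlation). Lymphotoxin genes LTB and LTA fell from 74.6 ± 6.50 to 24.6 ± 1.66 CPM and by a log2 change of 2.42 ± 0.25, NFKB1 by 1.57 ± 0.19 and the adhesion molecule ICAM1 by 1.65 ± 0.22. Of 16 genes of MHC class I and antigen presentation 9 fell and 1 rose (9 and 2 adjusted over the list alone; camera adjusted p = 0.035, and adjusted p = 0.86 with an estimated correlation), with the immunoproteasome subunits PSMB8 (-1.11 ± 0.10) and PSMB10 (-0.81 ± 0.13), the peptidase ERAP2 (-0.96 ± 0.10) and TAPBP (-0.56 ± 0.09). The call on that list was lost with the block (0.056), without JQ1 replicate 3 (0.12) and without DMSO replicate 2 (0.066). With the block 3 of its genes were higher and 10 lower.

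Histone genes rose. Of 39 tested replication-dependent histone genes 16 rose and 2 fell (17 and 2 adjusted over the list alone), and the block called 26 higher and 3 lower. Their median was 0.38 (camera adjusted p = 0.0017, and adjusted p = 0.86 with an estimated correlation). The median was 0.21 without JQ1 replicate 3, and the call was lost with fry (adjusted p = 0.18). H1-4 rose from 1096 ± 99.6 to 1786 ± 228 CPM, H4C3 from 721 ± 72.2 to 1138 ± 148 CPM and H4C8 from 495 ± 29.5 to 845 ± 126 CPM, while H2BC3 fell by 0.76 ± 0.11. Of 12 histone genes that also give polyadenylated or replacement transcripts 7 rose and 0 fell (the same adjusted over the list alone; median 0.46, camera adjusted p = 0.0042, and adjusted p = 0.86 with an estimated correlation). They included the linker histone H1-10 (0.91 ± 0.10), the replacement histones H3-3B (0.85 ± 0.12) and H3-3A (0.71 ± 0.12), and H2BC5 (0.84 ± 0.16). Histone genes have near-identical copies, so their levels are uncertain where reads fit several.

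Genes of DNA replication and G1/S rose in 8 of 35 cases and fell in 0 (5 and 0 adjusted over the list alone; median 0.29, camera adjusted p = 0.024, and adjusted p = 0.86 with an estimated correlation). CLSPN, a checkpoint mediator, rose from 112 ± 21.9 to 211 ± 36.9 CPM, GINS4 of the replicative helicase by 0.76 ± 0.15, the histone mRNA binding gene SLBP by 0.76 ± 0.17 and CDK2 by 0.56 ± 0.14. The call on the list was lost without JQ1 replicate 1 (camera adjusted p = 0.074), JQ1 replicate 3 (0.12, median 0.16) or DMSO replicate 2 (0.37, median 0.09) and with fry (0.46). The block called 23 genes higher and 3 lower. Of 33 mitosis and G2/M genes edgeR called 0 in either direction, also when adjusted over the list alone (camera adjusted p = 0.34), with 4 higher and 0 lower at an unadjusted p under 0.05, 2 higher by DESeq2 and 1 by limma-voom. For this list the block called 16 higher and 4 lower, and without DMSO replicate 2 it was called higher (camera adjusted p = 0.0065, and adjusted p = 0.88 with an estimated correlation over all libraries). CDK1, for example, had 177 ± 53.7 CPM in DMSO and 259 ± 35.6 in JQ1 (0.55 ± 0.20, edgeR adjusted p = 0.064, and 2.9e-06 with the block, 0.0031 without DMSO replicate 2; DESeq2 adjusted p = 0.013 and limma-voom 0.04998). Among CDK inhibitors and D cyclins 3 of 13 rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.28). In this list 8 were higher and 3 lower under the block. CDKN2D, which inhibits CDK4 and CDK6, rose by 1.15 ± 0.16 and the antiproliferative gene BTG1 by 0.94 ± 0.16. CDKN1A was too rare to test, with 10 counts over the 6 libraries.

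**Figure D3:**
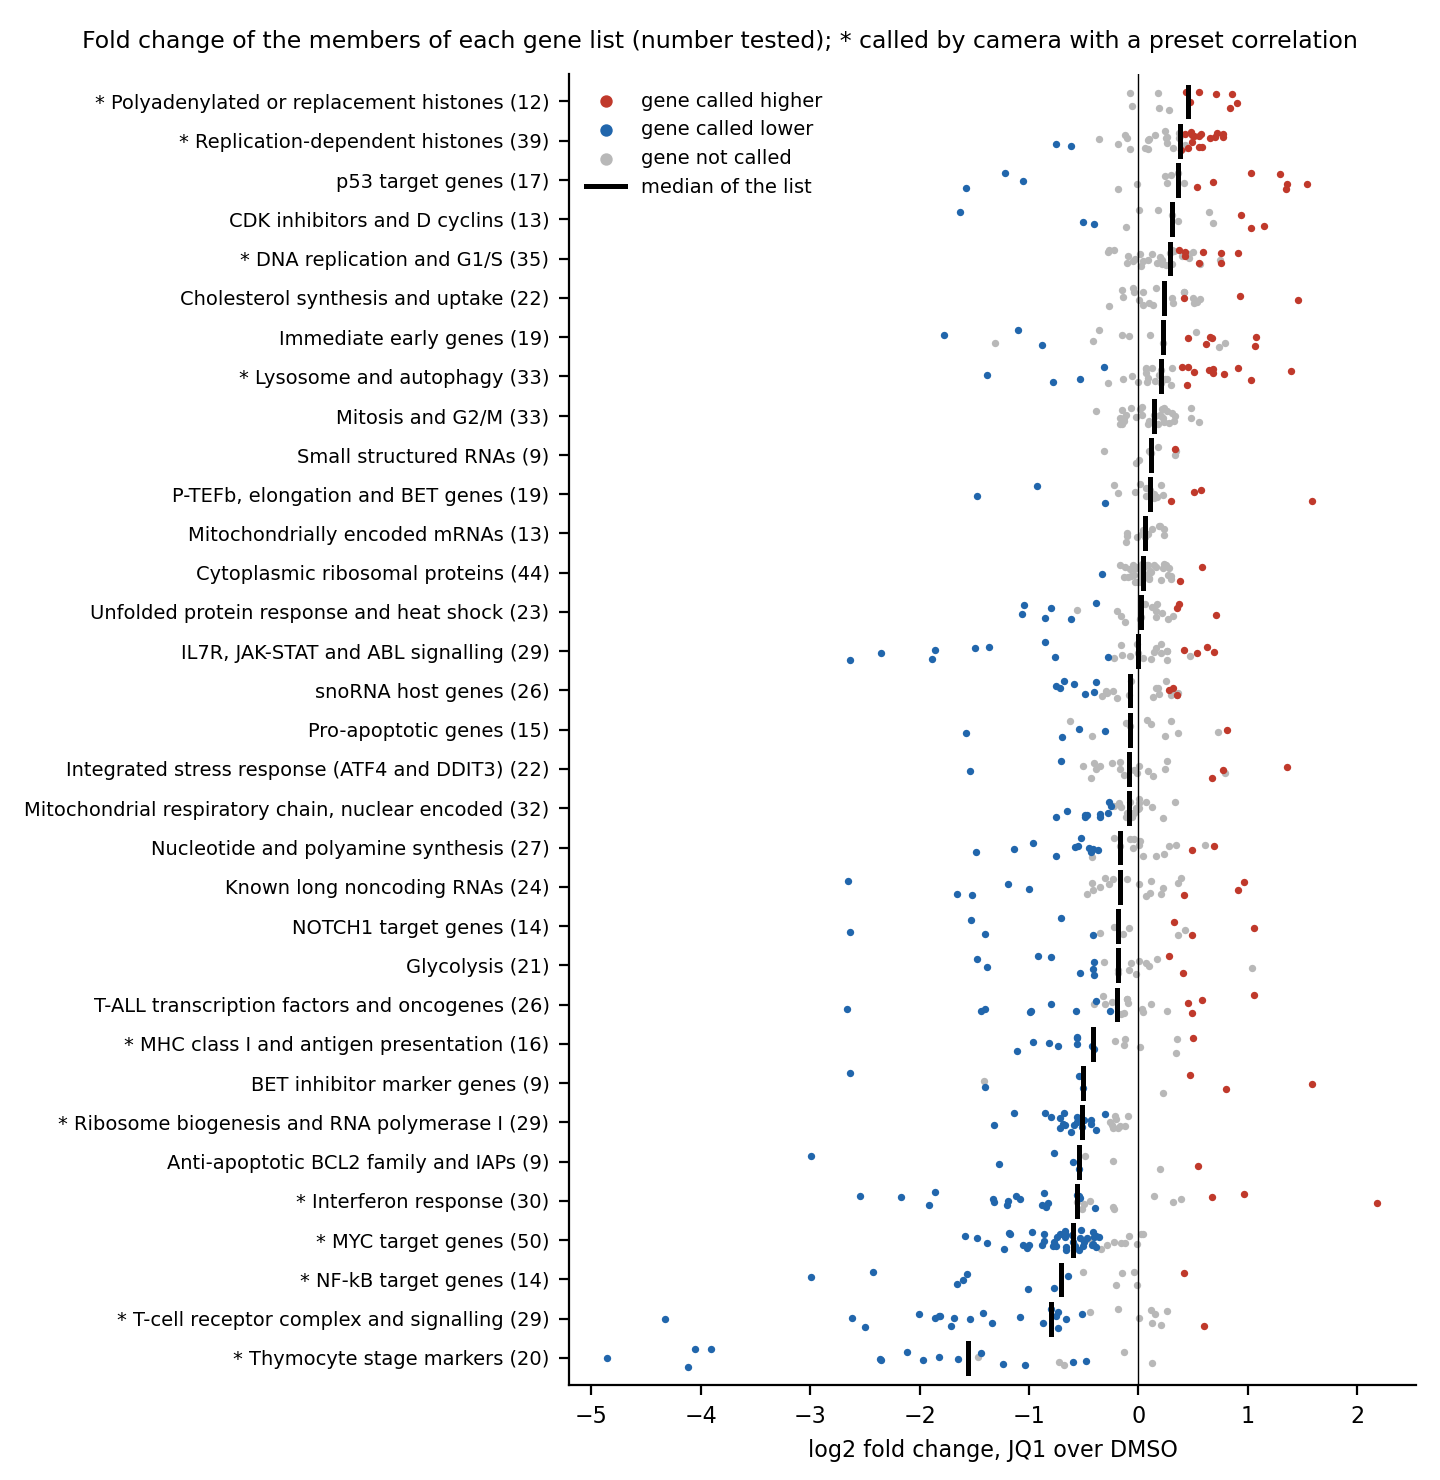
Each point is a tested member of one of the 33 gene lists, placed by its log2 fold change (JQ1 over DMSO), with red and blue for edgeR adjusted p under 0.05; the black bar is the median of the list. Asterisks mark the 11 lists called by camera with a preset correlation, from thymocyte stage markers (median -1.56) to the polyadenylated or replacement histones (median 0.46); 0 are called with an estimated correlation.

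Apoptosis genes moved in both directions. Of 9 anti-apoptotic BCL2 family and IAP genes 5 fell and 1 rose (7 and 1 adjusted over the list alone; camera adjusted p = 0.06). The list was called lower without JQ1 replicate 2 (camera adjusted p = 0.036), without DMSO replicate 3 (0.047), with no filter on low counts (0.015), with unstranded counts (0.034) and by fry (0.018), and had adjusted p = 0.86 with an estimated correlation over all libraries. CFLAR, the inhibitor of caspase activation at death receptors, fell by 1.27 ± 0.13 and BCL2L1 by 0.60 ± 0.12. BCL2A1 fell from 0.813 ± 0.113 to 0.0954 ± 0.0402 CPM (59 counts in DMSO and 6 in JQ1). MCL1 rose from 202 ± 22.1 to 295 ± 4.17 CPM (edgeR adjusted p = 0.0022). Of 15 pro-apoptotic genes 4 fell and 1 rose (the same adjusted over the list alone, camera adjusted p = 0.65). In this list the block called 5 higher and 4 lower. The death receptor FAS fell by 1.58 ± 0.23, BID by 0.54 ± 0.08 and BIK by 0.70 ± 0.13. APAF1, the apoptosome scaffold, rose by 0.81 ± 0.10. BCL2L11 had a log2 change of 0.24 ± 0.14 (edgeR adjusted p = 0.2, and 0.005 with the block). Its change was 0.42 without DMSO replicate 2 (edgeR adjusted p = 0.023) and 0.14 without DMSO replicate 3. Of 17 p53 target genes 7 rose and 3 fell (the same adjusted over the list alone; camera adjusted p = 0.12, 0.016 with no filter on low counts, 0.01 by fry, and adjusted p = 0.86 with an estimated correlation), with the sestrins SESN1 (1.29 ± 0.10) and SESN2 (1.36 ± 0.15) and the repair gene XPC (0.69 ± 0.09) higher and the nuclease AEN (from 56.2 ± 5.39 to 27.1 ± 4.54 CPM) lower.

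Stress and degradation genes gave a further called list. Of 33 lysosome and autophagy genes 11 rose and 4 fell (the same adjusted over the list alone), and the block called 17 higher and 5 lower. Their median was 0.21 (camera adjusted p = 0.024, and adjusted p = 0.86 with an estimated correlation). NEU1, a lysosomal sialidase, rose from 35.0 ± 6.19 to 91.9 ± 19.1 CPM, the autophagosome gene MAP1LC3B by 0.91 ± 0.12, the proton pump subunit ATP6V0D1 by 0.69 ± 0.10 and ATG2A by 0.68 ± 0.10. The call on the list was lost without JQ1 replicate 2 (camera adjusted p = 0.12), without DMSO replicate 3 (0.1) and with fry (0.1). In the integrated stress response 3 of 22 genes rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 0.84), with PPP1R15A (0.77 ± 0.12) and PSPH (0.68 ± 0.14) higher and TRIB3 (-1.54 ± 0.30) lower. Its median of -0.09 and mean of -0.03 had the opposite sign to its test, and the block called 5 higher and 7 lower. In the unfolded protein response and heat shock list 6 of 23 fell and 3 rose (the same adjusted over the list alone; camera adjusted p = 0.84), with a median of 0.03 and a mean of -0.12. The foldase gene PDIA6 fell by 0.85 ± 0.10, HSPB1 by 1.06 ± 0.15 and SDF2L1 from 14.04 ± 1.52 to 6.77 ± 0.893 CPM. HSPA1B, which has a near-identical copy, rose by 0.71 ± 0.17, and in this list the block called 7 higher and 8 lower. Of 19 immediate early genes 6 rose and 3 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.44), among them JUND (0.46 ± 0.09), PHLDA1 (0.68 ± 0.16), DUSP2 (-1.10 ± 0.15) and SPRY1 (-1.77 ± 0.37). TXNIP, which restrains glucose uptake, had 159 ± 78.8 CPM in DMSO and 262 ± 110.1 in JQ1 (0.73 ± 0.42, edgeR adjusted p = 0.23, and 3.1e-08 with the block). The TXNIP change was 1.20 without DMSO replicate 2 (edgeR adjusted p = 0.047), 0.46 without DMSO replicate 3 and 0.33 without JQ1 replicate 2.

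Because total RNA was sequenced, long noncoding RNAs (lncRNAs) were measured with or without a poly(A) tail. LUNAR1, a NOTCH-regulated lncRNA on chromosome 15 (99028538 to 99031053), rose 1.88-fold, to 40.7 ± 6.08 CPM (log2 change 0.91 ± 0.16, edgeR adjusted p = 0.0017). NEAT1, the paraspeckle RNA, rose from 62.6 ± 5.43 to 122 ± 14.5 CPM (0.96 ± 0.11, edgeR adjusted p = 0.00012). MALAT1 had 1902 ± 212 CPM in DMSO and 2489 ± 329 in JQ1 (0.39 ± 0.14, edgeR adjusted p = 0.057). It passed the threshold in edgeR with the block (8.8e-05), without JQ1 replicate 2 (0.03) and without DMSO replicate 1 (0.045) and with a filter at 1 CPM in 3 libraries (0.046). It also passed with DESeq2 (adjusted p = 0.0099) and limma-voom (adjusted p = 0.049). PVT1, the neighbour of MYC, was listed at 0 in all 6 libraries and for either strand and was not tested. Reads that fit several genes are not counted, so the 0 does not show that it was silent. The largest lncRNA falls were in MIR3142HG (-4.06 ± 0.64, from 83 counts in DMSO and 4 in JQ1), AL161644.1 (-3.81 ± 0.53, from 88 and 5 counts), AP000345.2 (-3.65 ± 0.56, from 125 and 8 counts), LINC00539 (-3.56 ± 0.29) and PCAT14 (-3.46 ± 0.33). With both strands counted together, AL161644.1 had a log2 change of -1.88 and LINC00539 of -2.19. The largest rises were in SPAG5-AS1 (2.15 ± 0.40), RAP2C-AS1 (1.98 ± 0.33), AKAP1-DT (1.93 ± 0.25), AC008543.3 (1.84 ± 0.35) and FLJ20021 (1.83 ± 0.35). Counted without strand, SPAG5-AS1 had 0.33 (edgeR adjusted p = 0.33) and RAP2C-AS1 0.87.

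Among 1866 tested lncRNA genes 245 rose and 212 fell (198 and 179 adjusted over the lncRNA genes alone), and the block called 431 higher and 304 lower. Falls were the more numerous with library size as the only scaling (193 higher, 226 lower), with no filter on low counts (275, 302), without JQ1 replicate 2 (195, 199) and without DMSO replicate 1 (176, 204). Without JQ1 replicate 3 both were 175. The direction differed from that of protein-coding genes: 53.6% of called lncRNA genes rose against 41.2% of called protein-coding genes (odds ratio 1.65, 95% interval 1.35 to 2.01, Fisher's exact test p = 3.6e-07, 2-sided, across genes, which are not independent). Called pseudogenes (64.1%), small RNA genes (69.2%) and other or unmatched genes (74.3%) rose more often still, so the difference was not particular to lncRNA genes. Against a fold change of 1.5, 42 lncRNA genes were higher and 72 lower, so lncRNA falls were the more frequent among larger changes. Of 24 lncRNAs known in leukaemia or transcription 5 fell and 3 rose (the same adjusted over the list alone; camera adjusted p = 0.52), including CYTOR (-1.66 ± 0.16), MIR155HG (-1.52 ± 0.20), the host of microRNA-155, and LINC-PINT (ENSG00000231721.6, -1.19 ± 0.16); the block called 6 higher and 10 lower. Of 26 snoRNA host genes 7 fell and 3 rose (the same adjusted over the list alone, camera adjusted p = 0.63). SNHG16 (-0.68 ± 0.10), SNHG20 (-0.75 ± 0.12), SNHG17 (-0.72 ± 0.14) and SNHG10 (-0.58 ± 0.12) were lower. Of the snoRNA host genes the block called 11 higher and 10 lower. Of 9 small structured RNAs of the 7SK, RNase P, RNase MRP, SRP and vault type SCARNA7 alone rose (0.33 ± 0.11), a call lost in 4 of the 6 fits without a library, with library size as the only scaling and with unstranded counts, and 0 fell (0 and 0 adjusted over the list alone; camera adjusted p = 0.52). In this group the block called 2 higher and 1 lower.

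The share of gene counts from lncRNA genes was 1.46% ± 0.0519 in JQ1 and 1.40% ± 0.0486 in DMSO (SD, n = 3; exact permutation test, 2-sided p = 0.3, where the smallest p that 3 against 3 allows is 0.1). MALAT1 held 0.244% ± 0.0359 of gene counts in JQ1 and 0.194% ± 0.0165 in DMSO, and without MALAT1 and NEAT1 the difference of the lncRNA share was 0.00104 percentage points in place of 0.0564. Over all lncRNA genes, the difference was 0.0285 without JQ1 replicate 1 and 0.0293 without DMSO replicate 1. Without mitochondrial and small RNA genes it was 0.112 (exact permutation test, 2-sided p = 0.1). Mitochondrial ribosomal RNA held 16.7% ± 1.75 in JQ1 and 14.6% ± 1.45 in DMSO, higher in 3 of 3 replicate pairs (exact permutation test, 2-sided p = 0.2). Of 13 mitochondrially encoded mRNAs edgeR called 0, also when adjusted over the list alone and at an unadjusted p under 0.05, as did DESeq2 and limma-voom (camera adjusted p = 0.37). They held 0.782% ± 0.0333 and 0.718% ± 0.0150 (exact permutation test, 2-sided p = 0.1), and the block called 4 of them higher.

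Markers of other cell types were mostly too rare to test. Myeloid markers summed to 0.222 CPM in JQ1 and 0.429 in DMSO, and erythroid and megakaryocyte markers to 0.569 and 0.339 CPM, with 0 of 12 genes of either list abundant enough to test. Of 12 B-cell markers 3 were tested and 2 fell (the same adjusted over the list alone). IGLL1, a surrogate light chain gene, fell from 11.2 ± 9.09 to 0.425 ± 0.158 CPM and CD79B from 8.80 ± 2.69 to 1.23 ± 0.411 CPM, and CD79A had 8.15 ± 4.13 CPM in DMSO and 2.94 ± 2.32 in JQ1 (edgeR adjusted p = 0.17, and 0.011 with the block). The NK-cell list had 1 tested member of 10, NKG7, a cytotoxic granule gene that T cells also express, with 180.0 ± 45.6 CPM in DMSO and 90.6 ± 46.5 in JQ1 (edgeR adjusted p = 0.11, and edgeR adjusted p = 0.054 when adjusted over the list alone, where 0 were called). The epithelial and fibroblast list had 1 tested member of 12, the receptor kinase gene PDGFRB, which fell from 9.16 ± 1.37 to 3.01 ± 0.472 CPM (also adjusted over the list alone).

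Over the 33 gene lists with at least 5 tested members, camera with a preset correlation of 0.01 called 4 higher and 7 lower, and with an estimated correlation it called 0, with 1 list at an unadjusted p under 0.05, while fry called 2 higher and 11 lower. Other splits of the 6 libraries into 3 and 3 called up to 11 lists in 1 direction. Each of those splits mixes the treatments unevenly and so keeps part of the treatment contrast. Their counts therefore cannot decide whether the list calls come from JQ1.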

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

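The test of opposite-strand reads was designed after the counts had been seen. Reads on the strand opposite to a gene were not used in the comparisons, and some of them rose under JQ1. Over 1464 well-counted genes with no annotated gene on the other strand within 10 kb, the median share of reads on that strand was 0.1%, so wrong-strand reads are rare. Of 193 genes with no annotated gene on the other strand within 10 kb and enough reads there to test, whatever their own level, 24 were higher and 15 lower in JQ1 than in DMSO (edgeR adjusted p under 0.05). The 5 with the smallest adjusted p among those that rose, had at least 1 CPM in JQ1 and at least 10% of their reads on the opposite strand, over both groups, and groups that do not overlap are given here.

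Opposite to AC093849.1 (GRCh38 chromosome 4, 173467833 to 173470041) the level was 2.78 ± 0.330 CPM in JQ1 and 0.642 ± 0.260 in DMSO (SD, n = 3), a log2 change of 2.08 (edgeR adjusted p = 5.8e-07), with 0 reads on the strand of AC093849.1 itself. Opposite to RPL5P11 (chromosome 4, 173419245 to 173420137), on the same chromosome nearby, the log2 change was 2.28 (edgeR adjusted p = 6.1e-06), again with 0 reads on its own strand. Opposite to NEIL2 (chromosome 8, 11769639 to 11787346), a DNA glycosylase gene, the log2 change was 2.02 (edgeR adjusted p = 5.8e-07), from 0.942 ± 0.222 to 3.89 ± 1.48 CPM. Opposite to ZNF487 (chromosome 10, 43436841 to 43483179) the log2 change was 2.01 (edgeR adjusted p = 6.1e-06), and opposite to VTI1BP2 (chromosome 4, 183483490 to 183484185) it was 1.74 (edgeR adjusted p = 5.5e-05).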

How the results depend on the processing

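The alternative of a replicate block together with an estimated correlation was chosen after seeing the data; the others were fixed before. The counts of called genes stayed within 1.5 times of the main counts under DESeq2, limma-voom, the 3 other scalings, both other filters, unstranded counts and without mitochondrial and small RNA genes; DESeq2 kept 94.5% of the 5110 calls in direction, library size only 89.6%, and unstranded counts 90.9% with 2 called the opposite way. Library size only moved the median log2 change of all genes to -0.06 and the share of calls that were higher from 43.6% to 34.3%. The replicate block raised the counts to 3813 genes higher and 4133 lower, and to 431 lncRNA genes higher and 304 lower. It kept 5106 of the 5110 calls, ended the call on MHC class I and antigen presentation and added cholesterol synthesis. Among named genes the block changed the calls of 16, all from not called to called, and it changed no other list call. The test against 1.5-fold, which asks for larger changes, called 246 genes higher, 899 lower, 42 lncRNA genes higher and 72 lower. For gene lists, an estimated correlation gave 0 higher and 0 lower with or without the replicate block, fry gave 2 higher and 11 lower, and no filter on low counts gave 11 lower; the cause was not tested. Leaving out each replicate in turn gave 1707 to 1901 genes higher, 2436 to 2627 lower, 175 to 223 lncRNA genes higher, 148 to 204 lower, 3 to 5 lists higher, 7 to 8 lists lower and a difference of the lncRNA share of 0.0285 to 0.0797 percentage points, and kept 77.1% to 81.4% of calls, with fewer samples in each fit. The lncRNA share difference stayed above 0 in each alternative, with exact p between 0.1 and 1, a design that cannot pass 0.05. Named genes were not compared under relative log expression or upper-quartile factors, no filter on low counts or the test against 1.5-fold. Over the other alternatives, 46 values of named genes lost the call, 34 gained it and 2127 kept their side. Lists were not compared under DESeq2, limma-voom, relative log expression or upper-quartile factors or the test against 1.5-fold. Over the rest, 33 values of lists lost the call, 23 gained it and 437 kept their side. For genes and lists 0 reversed. With every library thinned to 15925885 gene counts, 13126 genes had enough reads to test in place of 13975.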

Other observations

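All tests of gene families by name stem were chosen after the data were seen; the predictions for the other tests in this part were written before their results. Genes of mitochondrial ribosomes that passed the test mostly fell. Of 49 tested genes whose symbols start with MRPL, the large subunit of the mitochondrial ribosome, 24 fell and 0 rose, with a median log2 change of -0.30 (camera adjusted p = 1.0e-05 over 66 families with at least 15 tested members, and adjusted p = 0.93 with an estimated correlation). Of 29 MRPS genes, the small subunit, 16 fell and 2 rose (median -0.34, camera adjusted p = 0.038), and of 16 TRMT genes, which modify transfer RNA, 7 fell and 0 rose (median -0.27, camera adjusted p = 0.038), both with adjusted p = 0.93 with an estimated correlation. These were the 3 families called, all lower. Among the others, centrosomal CEP genes had 11 of 36 higher and 5 lower (camera adjusted p = 0.057).

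Falls outnumbered rises among changes over 2-fold by 2.73 to 1. The choice among common scalings did not account for it: over relative log expression, upper-quartile and library-size scaling and without mitochondrial and small RNA genes, the lowest ratio was 2.54. These scalings moved the median log2 change of all genes only to between -0.06 and 0.02, so a larger scaling error was not tested. Depth is argued against as the whole cause: with every library thinned to 15925885 gene counts the ratio was 2.78 (970 lower and 349 higher). A change in total RNA per cell cannot be told apart from the effect, since no added RNA standard was read here; a uniform log2 shift of 0.28 would balance both directions. An effect of JQ1 stays open beside it.

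T-cell receptor and thymocyte genes fell together, with 35 of 49 lower and 1 higher and a median of -1.24. Other cells mixed into the JQ1 libraries would lower all members alike, but the SD of the log2 changes over members was 6.58 times their median SE, and the median would need 57.7% of other cells. In JQ1 the summed markers were 0.222 CPM for myeloid, 0.569 for erythroid, 3.26 for epithelial and fibroblast, 4.91 for B cells (29.1 in DMSO, so these fell too) and 90.7 for NK cells (180.2 in DMSO), the last nearly all from NKG7, which T cells also express. Gene length and GC content also leave the pattern: after a smooth adjustment for both, the median was -1.14. A lower expression of T-lineage genes under JQ1 may be biological, as a hypothesis found and tested on the same data.

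Called lncRNA genes rose more often than called protein-coding genes (53.6% against 41.2%), as under each alternative, with the smallest gap without DMSO replicate 1 (46.3% against 40.8%). The difference was not particular to lncRNA genes. Among called pseudogenes 64.1% rose, among called small RNA genes 69.2% and among other or unmatched genes 74.3%. Low expression argues in the other direction: among called protein-coding genes matched on abundance, 28.6% rose (the central 95% of 1000 draws ran from 25.4% to 31.7%). Read-through from a coding gene that ends up to 10 kb upstream also leaves the difference. Among the 393 lncRNA calls with no such gene 55.0% rose (exact 95% interval 49.9% to 60.0%), and 45.3% among the 64 with one. The check did not remove lncRNA genes that overlap a coding gene on the same strand, so reads from such a gene were not tested as a cause. A difference in how the classes respond to JQ1 stays open and was not tested otherwise.

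Shared regulation of neighbours was tested as a hypothesis over 1750 pairs of a lncRNA gene and the nearest coding gene within 100 kb. The Spearman correlation of their log2 changes was 0.26 (p = 0.0001 from shuffled pairs, the smallest the shuffles can give, across genes, which are not independent). A correlation beyond shuffled pairs was the outcome predicted under shared regulation. The value differed by layout: it was 0.64 for 394 pairs that overlap on the same strand, where intronic reads may be shared, 0.38 for 327 pairs apart on the same strand, 0.17 for 161 pairs apart on opposite strands and 0.10 for 658 pairs that overlap on opposite strands (Benjamini-Hochberg adjusted p = 0.0002, 0.0002, 0.038 and 0.02). Pairs on the same strand correlated most, so the pooled value cannot tell shared regulation from read-through or shared reads along a strand. A shared divergent promoter did not account for the pooled correlation. The 210 pairs back to back within 1 kb had a correlation of 0.03 (adjusted p = 0.63 from shuffled pairs), and the difference from the other pairs was -0.25 (p = 0.0007 from shuffled pair classes).

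The 6 libraries make 10 splits into 3 and 3, so no split count can give a share under 0.05. The real split, 1 of 10 with as many calls, gave 2227 genes higher, 2883 lower, 245 lncRNA genes higher and 212 lower, and the highest of the other splits gave 0 for each. Each other split has both treatments on each side, so the treatment difference adds to the spread within its groups. It also keeps part of the treatment contrast between its groups. Neither the 0 gene calls nor the list calls of the other splits therefore test the treatment. For gene lists the real split gave 4 higher and 7 lower; 10 of 10 splits had at least 4 lists in 1 direction, 7 of 10 had at least 7, and the highest other split had 11. Of the 3 other splits that also part all replicate pairs, the list counts in the 2 directions were 1 and 7, 2 and 5, and 4 and 9; the other 6 splits part 1 pair each.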
